A study of Mus musculus with 8 samples.

How the data were processed

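Expression was measured in 32Dcl3 cells transduced with the empty vector (mock) or with the vector carrying ASXL1-MT, in IL-3 and after 2, 6 and 24 h in G-CSF, on 8 Affymetrix mouse arrays, 1 per condition. The design text names the A array of the mouse set, while the table holds 45037 probe sets, more than that array carries. The design text gives 5 µg of total RNA and the protocol 3 µg. The labels do not give the species of the ASXL1 cDNA, whether IL-3 was withdrawn when G-CSF was added, or whether the time points were separate cultures.

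The deposited values are taken as log2 expression of each probe set minus the median of that probe set over the 8 arrays; every probe set's median was within 5e-07 of 0. Per the labels, intensities were captured with MAS 5.0, and the submitters' processing notes name RMA without a version. The centring, the log base and the scaling between arrays are not given in the sources used here. A base of 10 is excluded by a range of up to 9.06 within a probe set. Base 2 was taken because RMA gives it, and a natural log was not excluded; under it every log2 difference would be 1.44 times larger. In 547 probe sets several arrays share the lowest value, and the origin of these ties was not tested. The values of dim probe sets vary more than RMA usually leaves: the median SD over the 8 arrays was 1.33 for 9293 probe sets at an estimated level under 4, 0.71 for 21865 at a level of 4 to 8, and 0.26 for 13879 at a level of 8 or more.

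Because the table is centred, the level of each probe set was estimated from the rounding step of its 32-bit numbers, which grows with the level before centring. On 8000 simulated probe sets the estimate had a median absolute error of 0.739 log2 units, and 96.0% fell on the correct side of the median simulated level. The filter on dim genes lies at another level, 6.23, for which this share was not measured. This step was chosen after seeing the data and departs from the design, which had assumed uncentred values. Of the probe sets, 34945 carried 1 gene symbol, 932 several and 9160 none, as the probe table pairs them. Each of 18193 genes was represented by the probe set with the highest estimated level rounded to a whole unit. Ties went to the more specific probe set type and then to the first name, and the rounding and tie rule were also set after seeing the data. The 12983 genes whose second-highest array value reached the median level of the table were tested. A stricter filter at the 70th percentile kept 7585 genes, called bright here.

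Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in 1 additive fit of the 8 arrays on time point and vector, with 3 residual degrees of freedom and a prior worth 1.16, and a Benjamini-Hochberg false discovery rate (FDR) of 0.05. All p-values given are from limma, two-sided, unless another test is named. The comparisons were ASXL1-MT against mock over the 4 time points, G-CSF at 2, 6 and 24 h against IL-3, and the ASXL1-MT effect at 24 h against the other time points through an added indicator, with 2 residual degrees of freedom. Errors are standard errors of the fit. The pair of cultures stands in for replicates of each time point, and the 4 time points stand in for replicates of the vector. At each time point alone there are 2 arrays and no test, and a size rule of 1 on the log2 scale was used. In simulated data with 200 changed genes, the fit recovered 50.5% of 2-fold and 77% of 4-fold changes between the vectors, and 0% of 2-fold and 68% of 4-fold changes at 24 h. Between the vectors 8 of 109 and 15 of 169 calls were false, shares above the FDR of 0.05. For 4-fold changes at 24 h 6 of 142 were false. All other genes were left unchanged, which makes the FDR harder to pass than in the real data at 24 h. There 3463 genes passed, of which 815 rose and 393 fell at least 2-fold, so the simulated shares do not describe that comparison.

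The comparisons, the alternatives, the rule for named genes and 28 gene lists were fixed before the data were examined. The lists hold 834 genes, of which 765 are on the array, 624 were tested and 64 are in more than 1 list. They cover neutrophil primary granules, secondary and tertiary granules, mature neutrophil surface and function, myeloid transcription factors, HOX genes and cofactors, the Polycomb and ASXL1 complex, STAT5 and IL-3 targets, STAT3 and G-CSF targets, G2 and M phase, DNA replication and S phase, ribosome biogenesis and MYC targets, cholesterol synthesis, the ATF4 amino acid response, the unfolded protein response, hypoxia and glycolysis, p53 targets, the BCL2 family, the interferon response, immediate early genes, integrins and adhesion, myeloid cytokine receptors, and markers of stem cells, mast cells with basophils and eosinophils, erythroid cells, megakaryocytes, monocytes with macrophages and dendritic cells, lymphoid cells and fibroblasts. Lists were tested with camera in limma at a preset correlation of 0.01, where the degrees of freedom come from the number of genes. Small p-values of that test therefore do not rest on replicate arrays. They were tested again with a correlation estimated from the same 3 residual degrees of freedom, on which that test then also runs. A call lost there does not by itself show members varying together, and does not exclude it. Both tests had p-values adjusted over the 28 lists of a comparison. At each time point a list's median was placed among 10000 random lists matched on level, as a percentile without a p-value.

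Named genes were, for ASXL1-MT against mock, the 12 largest differences in each direction with the same sign at all 4 time points, those past the FDR first. For G-CSF they were the 10 largest in each direction at 24 h and the 5 largest at 2 and at 6 h, and for the difference at 24 h the 5 largest in each direction. Asxl1, the Hoxa genes, Meis1, Clec5a and members of the lists were named besides these. Predicted genes without a name were passed over.

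The alternatives were quantile normalization, centring of each array, no filter or the stricter one, the mean of a gene's probe sets, all probe sets, eBayes with a trend and robust, no block, a fit of the 4 arrays of a contrast alone, each array or time point left out in turn, and another size rule. Quantile normalization ran on the estimated levels, where 29.4% of probe sets lie within 1 unit of level 12, so that it also evens out the spread of the centred values between arrays. Contrasts of 6 h with 2 h and of 24 h with 6 h, further list tests and the bright-gene correlations were chosen after seeing the data. So were the list tests with an array or a time point left out, with a stricter filter on dim genes and with quantile normalization again, and the lists and their members with the mean of the probe sets of a gene. Array medians over the tested genes lay between -0.042 and 0.054. One gene among the differences ranked by size is not reported here. Gene set enrichment with the database named in the design text was not run. Levels were estimated with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9.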

Results

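Gene expression was measured in 32Dcl3 cells, a mouse myeloid progenitor line that grows in interleukin-3 (IL-3) and matures toward neutrophils in granulocyte colony-stimulating factor (G-CSF). The cells carried an empty retroviral vector (mock) or the same vector with FLAG-tagged mutant ASXL1 (ASXL1-MT). ASXL1 is a chromatin regulator that is mutated in myeloid neoplasms. Each of the 2 cultures was profiled in IL-3 and after 2, 6 and 24 h in G-CSF on 1 Affymetrix array per condition, 8 arrays in all, and their number limits the precision. No condition was replicated, and the p-values may measure the technical spread between arrays only. Changes are log2 differences ± the standard error from limma, over 2 arrays on each side for G-CSF and 4 for ASXL1-MT, on a scale whose base of 2 was assumed. Of 18193 genes on the array, 12983 were bright enough to test.

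After 24 h in G-CSF, a comparison that asks how the cells respond to the cytokine, transcripts of neutrophil granule proteins and receptors rose. Of 18 secondary and tertiary granule genes 15 rose and none fell, and 15 were higher adjusted over the list alone. Lrg1, a secreted granule glycoprotein, rose by 5.25 ± 0.24, Ngp, a granule protein, by 4.95 ± 0.26, haptoglobin (Hp) by 4.92 ± 0.11 and the siderophore-binding lipocalin Lcn2 by 4.33 ± 0.16. Of 31 mature neutrophil genes 27 rose (28 adjusted over the list alone), among them the endotoxin co-receptor Cd14 (3.73 ± 0.27), the MYC antagonist Mxd1 (3.47 ± 0.12) and the G-CSF receptor Csf3r (2.16 ± 0.10). Of 26 STAT3 and G-CSF targets 18 rose (18 adjusted over the list alone), including the chemokine receptor Ccr1 (4.77 ± 0.16) and the feedback inhibitor Socs3 (3.16 ± 0.13). Of 24 myeloid cytokine receptors 18 rose (20 adjusted over the list alone). With camera these 4 lists were called up at adjusted p of 3.61e-09, 1.21e-12, 3.4e-08 and 3.38e-08, and each kept its call with an estimated correlation (adjusted p = 0.0423).

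The cholesterol synthesis and ribosome biogenesis lists moved down at 24 h. Of 20 cholesterol synthesis genes 15 fell (16 adjusted over the list alone), such as the sterol demethylase Cyp51 (-1.69 ± 0.16) and the isomerase Idi1 (-1.54 ± 0.08). With the mean of all probe sets of a gene 8 fell, and camera also called the list. The list was called at a camera adjusted p of 5.95e-09, or an adjusted p = 0.0423 with an estimated correlation. Of 40 ribosome biogenesis and MYC target genes 33 fell (36 adjusted over the list alone), with spermidine synthase Srm at -1.87 ± 0.10 and the nucleolar protein Nolc1 at -1.68 ± 0.09. That list's adjusted p was 1.51e-18, and the call was lost with an estimated correlation (adjusted p = 0.1). Of 31 ATF4 amino acid response genes 15 fell and 2 rose, led by the serine synthesis enzyme Phgdh (-1.07 ± 0.10), at an adjusted p of 0.00023 (adjusted p = 0.108 with an estimated correlation). Of these genes 9 fell and 1 rose with the mean of all probe sets, and camera also called the list. Of 43 S phase genes 5 fell and 2 rose, at an adjusted p of 0.0199 (adjusted p = 0.248 with an estimated correlation), and the call was also lost without the ASXL1-MT array at 24 h (adjusted p = 0.0872). The list tests without single arrays or time points and on probe set means, here and throughout, were chosen after seeing the data. In 2 further alternatives chosen so, it was also lost, with a stricter filter on dim genes (adjusted p = 0.0785) and with quantile normalization again (adjusted p = 0.0551). Adjusted over the list alone, 15 ATF4 response genes were lower and 3 higher, and 1 S phase gene was lower and 1 higher.

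All 13 primary granule genes passed the test at 24 h, 10 upward and 3 downward. Lysozyme Lyz1 rose by 3.55 ± 0.15, neutrophil elastase Elane by 2.26 ± 0.14 and myeloperoxidase Mpo by 0.49 ± 0.09, while the protease inhibitor Serpinb1a changed by -0.76 ± 0.14, and Ctsc and Gusb also fell. Averaged over its probe sets Serpinb1a did not pass (adjusted p = 0.0524), and Ctsc measured -1.62. The list was called up at an adjusted p of 0.00869 (adjusted p = 0.331 with an estimated correlation). Of 30 myeloid transcription factors 13 rose, among them Cebpd (2.40 ± 0.10), Spi1 (1.45 ± 0.12) and Gfi1 (1.39 ± 0.10), and the erythroid and megakaryocytic repressor Gfi1b fell (-2.87 ± 0.20). The mean of the 2 probe sets of Cebpd was 1.13 and did not pass (adjusted p = 0.177). The list was called up at an adjusted p of 0.00265 (adjusted p = 0.108 with an estimated correlation). Of 28 hypoxia and glycolysis genes 18 rose and 1 fell, including the mitophagy receptor Bnip3 (1.84 ± 0.12) and the glucose transporter Slc2a3 (1.79 ± 0.09). They were called up at an adjusted p of 1.86e-06 (adjusted p = 0.1 with an estimated correlation). Of 31 interferon response genes 14 rose and 1 fell, at an adjusted p of 0.00537 (adjusted p = 0.156 with an estimated correlation). Of 29 integrin and adhesion genes 11 rose and 1 fell, at an adjusted p of 0.0151 (adjusted p = 0.152 with an estimated correlation). Adjusted over the list alone, the members higher and lower were 10 and 3 for primary granules, 13 and 2 for transcription factors, 20 and 1 for hypoxia and glycolysis, 14 and 1 for interferon response and 12 and 1 for integrins.

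Weaker calls were made at 24 h for the BCL2 family (9 of 22 higher, 3 lower; adjusted p 0.0462), immediate early genes (10 of 26 higher, 3 lower; adjusted p 0.0474) and G2 and M phase genes (9 of 37 higher; adjusted p 0.0301). With an estimated correlation their adjusted p was 0.194, 0.194 and 0.646. Adjusted over the list alone, 11 BCL2 family genes were higher and 3 lower, 11 immediate early genes higher and 3 lower, and 9 G2 and M phase genes higher. The BCL2 call was lost without the ASXL1-MT array at 24 h (adjusted p = 0.0624), the mock array in IL-3 (0.105) or the mock array at 24 h (0.066). It was also lost with each array centred on its median (adjusted p = 0.0529). A stricter filter on dim genes, chosen after seeing the data, ended it too (adjusted p = 0.0584), as did the mean of all probe sets of a gene (adjusted p = 0.0948). The immediate early call was lost without the same arrays (adjusted p = 0.0639, 0.0934 and 0.0633), and its median of 0.40 was 0.67 with the stricter filter. It was also lost with the mean of all probe sets (adjusted p = 0.0832). The G2 and M phase call was lost without the mock array in IL-3 (adjusted p = 0.131) or at 24 h (adjusted p = 0.357), and with each array centred on its median (adjusted p = 0.0731), where its median was 0.15 against 0.23.

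**Figure D1:**
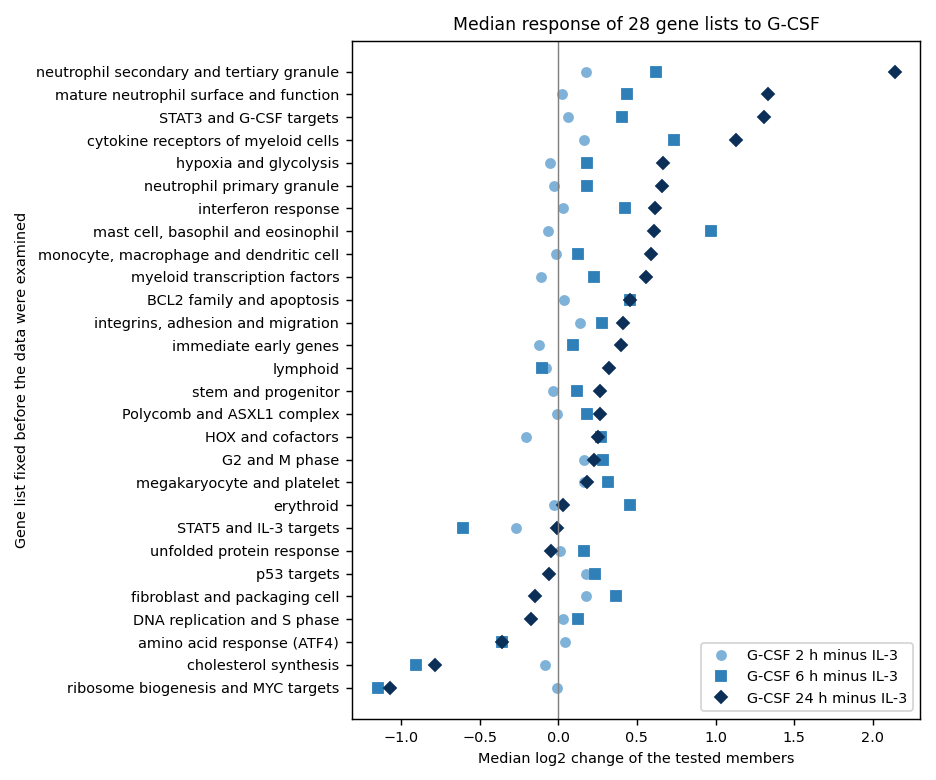
Median log2 change of the tested members of each of 28 gene lists after 2, 6 and 24 h in G-CSF against IL-3, from limma over both cultures; circles, squares and diamonds are the time points. The secondary and tertiary granule list has the highest median at 24 h (2.14) and the ribosome biogenesis and MYC target list the lowest (-1.07).

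The 10 genes with the largest rises at 24 h were Wfdc17 (7.29 ± 0.38), the eosinophil granule proteins Prg2 (6.51 ± 0.47) and Prg3 (5.91 ± 0.45), the macrophage pore-forming protein Mpeg1 (5.46 ± 0.91), Mtus1 (5.44 ± 0.35), Lrg1, Ngp, Hp, the lipopolysaccharide-binding protein Lbp (4.88 ± 0.14) and E-selectin Sele (4.86 ± 0.19). The 10 largest falls were in Hdac9 (-5.07 ± 1.11), a histone deacetylase, the cytokines Il6 (-4.91 ± 1.05) and Ccl3 (-4.20 ± 0.79), and Ttc30a1, Rasgef1b, Ankrd36, Usp17la, Txnrd3, Pnoc and Lgi2 (between -4.14 and -3.64). Estimated levels, as means over the 8 arrays, ran from 4.5 (Wfdc17) to 11.1 (Lrg1 and Hp). Those of Wfdc17, Sele, Hdac9, Ttc30a1, Pnoc and Lgi2 lay under 6.23, the median of the table, where values vary more between arrays. The other genes lay above it. With the mean of all probe sets of a gene, Ankrd36 (-2.53, adjusted p = 0.103) and Lgi2 (-1.13, adjusted p = 0.183) did not pass, and Hdac9 measured -2.997 and Txnrd3 -1.87. Without the filter on dim genes Hdac9 (adjusted p = 0.0742), Il6 (0.0714) and Ccl3 (0.0571) did not pass, and without the mock array at 24 h Il6 measured -3.17. In all, 1922 genes rose and 1541 fell at 24 h, of which 815 and 393 did so at least 2-fold. No gene passed without either IL-3 array or either 24 h array (0 of 12983 with limma; smallest adjusted p 0.0574 to 0.0631, with 3925 to 4115 genes at an unadjusted p under 0.05). Without either 6 h array 2144 passed. A fit of these 4 arrays alone also called 0 genes with limma, with 4149 at an unadjusted p under 0.05.

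**Figure D2:**
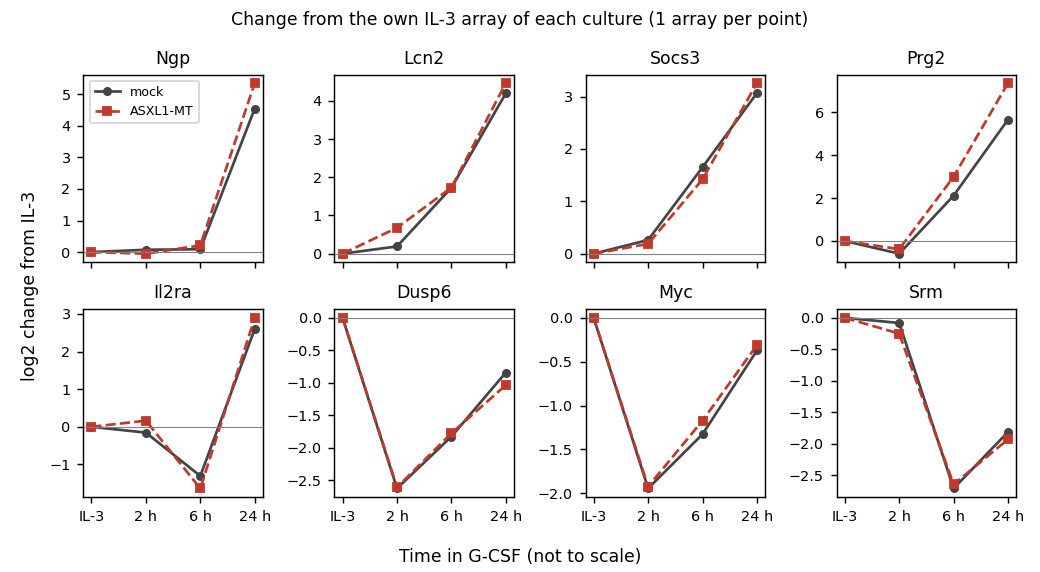
Log2 change of 8 genes, chosen after seeing the data, from the IL-3 array of the same culture, against time in G-CSF (not to scale); circles are mock, squares ASXL1-MT, 1 array per point. Ngp and Prg2 are highest at 24 h, while Dusp6 and Myc are lowest at 2 h and Srm at 6 h in both cultures.

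After 6 h in G-CSF the ribosome biogenesis and cholesterol lists had already moved down. Of 40 ribosome biogenesis and MYC target genes 32 fell (33 lower and 1 higher adjusted over the list alone), with Srm at -2.67 ± 0.10 and the nucleolar helicase Ddx21 at -2.05 ± 0.08. The camera adjusted p was 3.01e-21, or an adjusted p = 0.146 with an estimated correlation. Of 20 cholesterol synthesis genes 13 fell (16 adjusted over the list alone), with Cyp51 at -1.66 ± 0.16, at an adjusted p of 2.38e-11 (adjusted p = 0.127 with an estimated correlation). Of 31 ATF4 response genes 11 fell and 1 rose, with the arginine transporter Slc7a1 at -2.13 ± 0.13 and Atf4 itself at -1.54 ± 0.12. This list was called down at an adjusted p of 2.56e-05 (adjusted p = 0.146 with an estimated correlation). Of 27 STAT5 and IL-3 targets 9 fell, among them the STAT5 feedback gene Cish (-2.40 ± 0.16), the ERK phosphatase Dusp6 (-1.80 ± 0.10) and Myc (-1.25 ± 0.08), and 6 rose, among them Bcl6 (2.23 ± 0.23) and Fos (2.15 ± 0.14). That list was called down at an adjusted p of 0.00533 (adjusted p = 0.292 with an estimated correlation). Adjusted over the list alone, 13 ATF4 response genes were lower and 2 higher, and 11 STAT5 and IL-3 targets lower and 6 higher.

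Of 20 mast cell, basophil and eosinophil genes 10 rose at 6 h and none fell (12 adjusted over the list alone), including Prg3 (4.16 ± 0.45), Prg2 (2.55 ± 0.47), the activating receptor Cd200r3 (2.15 ± 0.14) and the interleukin-5 receptor Il5ra (1.89 ± 0.18). The mean of the probe sets of Cd200r3 was 1.12. The list's median of 0.97 was 0.61 without the filter on dim genes. The list was called up at an adjusted p of 0.00104 (adjusted p = 0.146 with an estimated correlation). Of 18 secondary and tertiary granule genes 11 rose, with Hp at 2.21 ± 0.11 and Lrg1 at 2.08 ± 0.24 (7 with the mean of all probe sets), at an adjusted p of 0.0016 (adjusted p = 0.146 with an estimated correlation). Of 31 mature neutrophil genes 13 rose and Trem1 fell (not with the mean of its probe sets, adjusted p = 0.126), at an adjusted p of 0.0113 (adjusted p = 0.197 with an estimated correlation). Of 24 cytokine receptors 12 rose and 1 fell, with the common beta chain Csf2rb at 1.70 ± 0.13, at an adjusted p of 0.000288 (adjusted p = 0.146 with an estimated correlation). The G2 and M phase list was called up with 6 of 37 members higher (adjusted p 0.000288, or an adjusted p = 0.476 with an estimated correlation). The BCL2 family list was called up with 8 of 22 higher and 1 lower (adjusted p 0.0297, or an adjusted p = 0.235 with an estimated correlation), but not without the mock array in IL-3 (adjusted p = 0.0526) or at 6 h (adjusted p = 0.0547). It was not called with a stricter filter on dim genes, chosen after seeing the data (adjusted p = 0.0747), or the mean of all probe sets (adjusted p = 0.179, median 0.26 against 0.46). The interferon response list was called up with 10 of 31 higher and 1 lower (adjusted p 0.0323, or an adjusted p = 0.258 with an estimated correlation), but not without the ASXL1-MT array in IL-3 (adjusted p = 0.0576) or the mock array at 6 h (adjusted p = 0.156). Adjusted over the list alone, the members higher and lower were 12 and 1 for secondary granules, 16 and 3 for mature neutrophils, 16 and 2 for cytokine receptors, 15 and 0 for G2 and M phase, 13 and 2 for the BCL2 family and 14 and 2 for interferon response.

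The 5 largest rises at 6 h were in Pate14 (4.47 ± 0.27), Sele (4.46 ± 0.19), Igk-V21, Prg3 and the growth factor Fgf17 (4.11 ± 0.33), and the 5 largest falls in the RNA-editing enzyme Adarb1 (-4.30 ± 0.44), Serpinb8 (-4.06 ± 0.74), Ttc29, Enpp3 and Prl3a1. Averaged over all probe sets Fgf17 (1.75, adjusted p = 0.151), Serpinb8 (-0.96, 0.466) and Enpp3 (-0.38, 0.628) did not pass, and Adarb1 measured -1.815. Without the filter on dim genes Serpinb8 (adjusted p = 0.0775) and Enpp3 (0.0687) did not pass. Apart from Prg3, all had estimated levels of 5.1 to 6.6, near the median of 6.23 of the table. In all, 1298 genes rose and 953 fell at 6 h, 449 and 345 of them at least 2-fold. Without either IL-3 array or either 6 h array limma called 0 genes, with 3189 to 3362 at an unadjusted p under 0.05, and without either 2 h array or either 24 h array it called 566 or 570. A fit of the 4 arrays alone called 0 genes with limma, with 3558 at an unadjusted p under 0.05.

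After 2 h in G-CSF the STAT5 and IL-3 target list was lower, at a median of -0.27 (-0.17 with the mean of all probe sets). Over all genes none of its 27 members passed; adjusted over the list alone, 5 were lower and 2 higher. Dusp6 measured -2.62 ± 0.10 (adjusted p 0.0575), Cish -2.15 ± 0.16, Myc -1.93 ± 0.08 and the cytokine Osm -1.50 ± 0.10. The list was called down at a camera adjusted p of 0.000134, and not with an estimated correlation (adjusted p = 0.426). The G2 and M phase list was called up at a median of 0.16 (adjusted p 8.22e-05, or an adjusted p = 0.443 with an estimated correlation) with none of 37 members passing over all genes or adjusted over the list alone, and lost its call without the ASXL1-MT array at 2 h (adjusted p = 0.0531) or the mock array in IL-3 (adjusted p = 0.0515, median 0.11). The p53 target list, with 1 of 24 members higher adjusted over the list alone, was called up at a median of 0.18 (adjusted p 0.0314, or an adjusted p = 0.426 with an estimated correlation), and lost its call without the ASXL1-MT array in IL-3 (adjusted p = 0.0712) or at 2 h (0.134), and without the mock array in IL-3 (0.166, where the median was 0.05) or at 2 h (0.132). It was also lost without the filter on dim genes (adjusted p = 0.119).

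Of the single genes at 2 h, Boll, a germ-cell RNA-binding protein, was lower by limma (-3.39 ± 0.10, adjusted p 0.0441), with 1064 genes at an unadjusted p under 0.05. The largest changes by size, none of which passed, were Uchl4 (5.06 ± 1.16), Thsd4 (4.38 ± 0.66), Fabp4 (4.19 ± 0.89), Marcks and Pate14 upward, and Maf (-4.20 ± 0.54), Ifng (-4.08 ± 0.79), Stk31 and Faxc downward. Apart from Faxc, at 10, their estimated levels were 4.5 to 5.9. Boll did not pass with any 1 of the 8 arrays left out, with adjusted p between 0.155 and 0.323, nor with its probe sets averaged (adjusted p = 0.417), nor without the filter on dim genes (adjusted p = 0.135). With the mean of all probe sets of a gene, Maf measured 0.03, Fabp4 0.53, Marcks 0.34, Thsd4 1.61, Faxc -0.49, Stk31 -2.47 and Boll -1.44. Without the mock array at 2 h Stk31 measured -2.58.

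The response was compared between the cultures across genes, which are not independent replicates. Pearson's r between the mock and the ASXL1-MT change from their own IL-3 arrays was 0.0173 at 2 h, 0.265 at 6 h and 0.381 at 24 h over the 12983 tested genes. Over the 7585 bright genes, a set chosen after seeing the data for this purpose, r was 0.12, 0.753 and 0.839.

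The comparison of ASXL1-MT with mock over the 4 time points asks what the mutant changes in these cells. With camera at its preset correlation, neutrophil gene lists lay lower and the ribosome biogenesis list higher in the ASXL1-MT culture, but no list was called with an estimated correlation. Limma called 0 of 12983 single genes (smallest adjusted p 0.249), with 843 at an unadjusted p under 0.05. Clec5a, a myeloid receptor that signals through DAP12, differed by -1.61 ± 0.28 (adjusted p 0.728), and was lower at 4 of 4 time points, by -0.72 in IL-3 and -1.56, -2.01 and -2.15 at 2, 6 and 24 h. Clec5a and the Hoxa genes were named because the study examined them on these samples, so that they are not independent evidence. The secondary granule list had a median of -0.23, with Ngp at -0.93 ± 0.18 and Wfdc21 at -0.47 ± 0.06, the 1 member lower adjusted over the list alone. The mature neutrophil list, which holds Clec5a, had a median of -0.16, with Cd14 at -0.90 ± 0.19 and the inhibitory receptor Pirb at -0.64 ± 0.12. Camera called these lists down at adjusted p of 8.9e-06 and 5.31e-05, and neither was called with an estimated correlation (adjusted p = 0.216 for both). With quantile normalization again the medians were -0.15 and -0.06.

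The ribosome biogenesis and MYC target list lay higher in the ASXL1-MT culture, at a median of 0.08 (adjusted p 8.9e-06, or an adjusted p = 0.362 with an estimated correlation), with Myc at 0.22 ± 0.06. With quantile normalization again its median was 0.04. The primary granule list lay lower at a median of -0.09 (adjusted p 0.0139, or an adjusted p = 0.399 with an estimated correlation), with Lyz1 at -0.55 ± 0.10 and Lyz2 at -0.49 ± 0.09, the 2 members lower adjusted over the list alone. Lyz2 measured -0.28 with quantile normalization again. The list was not called without the 2 h (adjusted p = 0.105, median -0.04) or the 6 h time point (adjusted p = 0.0821), and its median was -0.14 without 24 h. The p53 target list lay lower (median -0.07, with the death receptor Fas at -1.21 ± 0.27) and the erythroid list higher (median 0.15, with Klf1 at 0.41 ± 0.09), both at an adjusted p of 0.0139, or an adjusted p = 0.297 with an estimated correlation. The p53 call was lost without the 6 h time point (adjusted p = 0.15), and the erythroid call without 2 h (0.0546), 6 h (0.0907) or 24 h (0.0563). The cholesterol list lay higher (median 0.09, adjusted p 0.0145) and the STAT3 and G-CSF target list lower (median -0.10, adjusted p 0.0353, with Ccr1 at -0.70 ± 0.12, or -1.29 for the mean of its probe sets), each at an adjusted p = 0.297 with an estimated correlation. The cholesterol call was lost with any 1 time point left out (adjusted p = 0.0563 to 0.0821), and the STAT3 call without 2 h (0.105), 6 h (0.0821) or 24 h (0.119, median -0.06). Without the filter on dim genes the cholesterol (adjusted p = 0.066) and erythroid calls (adjusted p = 0.332) were lost. With quantile normalization again, chosen after seeing the data for the lists, the STAT3 (adjusted p = 0.584, median -0.04), cholesterol (0.169, median 0.05) and primary granule calls (0.0792) were lost. The mean of all probe sets ended the STAT3 (adjusted p = 0.116, median -0.02), cholesterol (0.0628) and p53 calls (0.0752). Against 8 lists with all arrays, 7 were called without IL-3, 4 without 2 h, 3 without 6 h and 5 without 24 h. Adjusted over the list alone, no member passed in the ribosome biogenesis, mature neutrophil, p53, erythroid, cholesterol or STAT3 list.

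**Figure D3:**
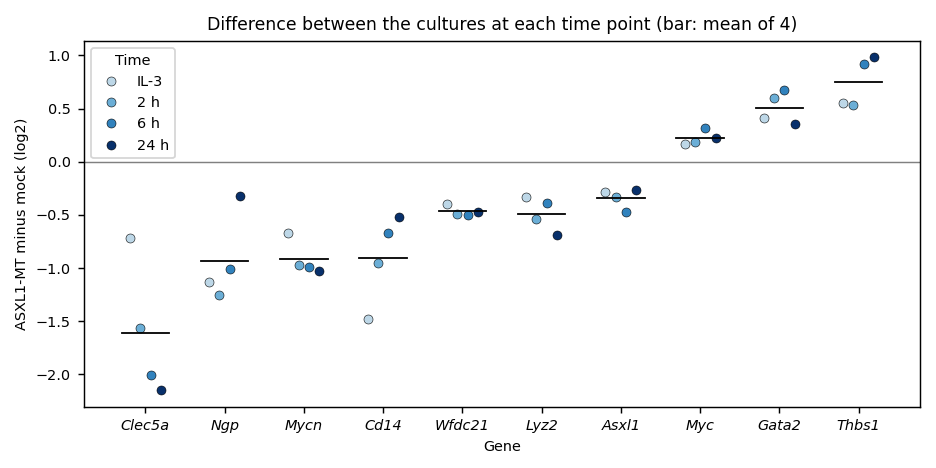
ASXL1-MT minus mock (log2) for 10 genes chosen after seeing the data; each point is 1 time point (2 arrays, 1 probe set per gene), and the bar is the mean of the 4. All 4 points of Clec5a, Ngp, Mycn, Wfdc21, Lyz2 and the Asxl1 probe set used lie below 0, and all 4 of Gata2 and Thbs1 above it. The differences of Mycn and Thbs1 rest on the probe set used. None of these genes passed the limma test over all genes.

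In lists that were not called, Mycn, a MYC family factor, differed by -0.91 ± 0.09 and the progenitor factor Gata2 by 0.51 ± 0.08, the 1 lower and 1 higher member of the stem and progenitor list adjusted over the list alone. Of the mast cell, basophil and eosinophil list (adjusted p 0.0944), 3 members were higher adjusted over the list alone, Gata2, the IgE receptor chain Ms4a2 (0.47 ± 0.07) and the basophil protease Mcpt8 (0.36 ± 0.07), and the mast cell chymase Cma1 was lower (-0.83 ± 0.17). Thbs1, a platelet matrix protein, was the 1 member of the megakaryocyte list higher adjusted over the list alone (0.75 ± 0.11). None of these passed over all genes. Averaged over their probe sets Mycn measured 0.32, Thbs1 0.01 and Ms4a2 0.31, so that the differences of Mycn and Thbs1 rest on the probe set used.

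The 3 probe sets of Asxl1 differed by -0.34 ± 0.09 (SD, n = 4 time points), -0.04 ± 0.04 and 0.68 ± 0.36, and the mean of the probe sets gave 0.10. Whether any of them reads the transgene is not given in the sources used here. Hoxa9, a homeobox factor of stem cell self-renewal, differed by -0.09 in IL-3 and by -1.75, 2.40 and 2.70 at 2, 6 and 24 h (mean 0.82, SD 2.12; 1.67 without 2 h, 0.29 without 6 h and 0.19 without 24 h). Its second probe set gave 1.67, 3.09, 2.78 and -2.21. Of the 41 genes in the HOX list 14 were bright enough to test, none passed the test, and camera did not call the list (adjusted p 0.691). A difference in these genes is not excluded. Hoxa3, Hoxa5 and Hoxa11os measured 0.18, -0.12 and 0.15, and Meis1, the HOX cofactor, -0.33 ± 0.23. The other 2 probe sets of Meis1 gave 0.058 and 0.101, and the means of the probe sets of Hoxa3 and Hoxa5 were -0.03 and -0.43. The second probe set of Hoxa11os, at an estimated level of 1.9, gave -1.13, in the other direction. The other Hoxa probe sets, of Hoxa2, Hoxa4, Hoxa7, Hoxa10, Hoxa11 and Hoxa13, lay below the filter on dim genes.

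By size, none passing the test, among the largest differences upward were Rbm46 (4.13 ± 0.19), Aqp3 (3.05 ± 0.47), a water channel, Hykk (3.03 ± 0.58), Sncg, Coro2b, Il12b, Psg16, Rnf133, Rin2, Mmp16 and Cspg4. Downward they were Tshz3 (-3.31 ± 0.36), Lrrc2 (-2.73 ± 0.58), Sgip1 (-2.63 ± 0.52), Ribc2, Abca13, Exoc3l2, Aknaos, Tmem132c, Plin4, Mucl1, Amigo1 and Sstr5 (-2.18 ± 0.79). Their estimated levels were 4.3 to 8.1. With the mean of all probe sets of a gene, Sgip1 turned to 0.61, Aqp3 measured 0.27, Hykk 1.165, Coro2b 1.26, Il12b 1.24, Mmp16 1.105 and Cspg4 1.32. Lrrc2 measured -0.71, Amigo1 -0.48, Abca13 -1.22, Exoc3l2 -1.16 and Tmem132c -1.23. Cspg4 measured 1.39 without IL-3, Ribc2 -1.70 without 2 h and Plin4 -1.51 without 6 h.

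At each time point alone, 1463, 1522, 1498 and 1476 genes differed by 1 or more on the log2 scale between the cultures in IL-3 and at 2, 6 and 24 h. Among the bright genes the rule took 47, 51, 44 and 45 higher and 48, 49, 34 and 41 lower. At all 4 time points, 16.9% of genes had the same sign, against 12.5% by chance. Across genes, Pearson's r of the difference between any pair of time points lay between -0.0105 and 0.0153, and between -0.0135 and 0.0931 among bright genes. The ribosome biogenesis list stood at percentiles of 99.9, 95.5, 100 and 99.7 of its random lists at IL-3, 2, 6 and 24 h, and the secondary granule list at 1.3, 12.1, 6.21 and 0.8. Other called lists were less even between time points. The primary granule list stood at 27.8, 0.3, 23.5 and 69.9, and the STAT3 and G-CSF target list at 36.15, 24.85, 56.7 and 2.47.

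The last comparison asks whether the ASXL1-MT effect at 24 h differed from that at the other time points. Limma called 0 of 12983 genes (smallest adjusted p 0.461), with 745 at an unadjusted p under 0.05. The difference for Clec5a was -0.72 ± 0.62. The largest by size, none passing, were Mmp1b (7.09 ± 2.72), Fam71e1, Spata16, Pou3f3 and Mcf2 upward, and Tmem184c (-7.15 ± 1.03), Ighv14-2, Gulp1, Npnt and Mmp10 (-6.20 ± 0.70) downward. Their estimated levels were 4.6 to 6.3. With the mean of all probe sets Fam71e1 measured 2.82, Spata16 2.82, Pou3f3 2.93, Tmem184c -2.87, Gulp1 -1.77 and Npnt -1.305. Of the 28 lists, tested for this comparison after seeing the data, the G2 and M phase list was called, lower by a median of -0.18 in the ASXL1-MT culture at 24 h, with 32 of 37 members below 0 (adjusted p 0.000739, or an adjusted p = 0.97 with an estimated correlation).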

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

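The list test of the ASXL1-MT effect at 24 h, and the 3 tests weighed here, were chosen only after the result was seen. The G2 and M phase list drew attention because camera in limma, at its preset correlation, called its ASXL1-MT effect different at 24 h (adjusted p 0.000739). With an estimated correlation camera did not call it (adjusted p = 0.97). The median of the list in ASXL1-MT minus mock stood at percentiles of 93.95, 96.1, 85.9 and 0 of its random lists at IL-3, 2, 6 and 24 h, and 32 of 37 members lay below 0 at 24 h against the other times.

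A uniform shift of whole arrays moves all genes alike, so it cannot make a call that sets the list against the other genes. The median of all tested genes moved by 0.0122 and that of the list by -0.184, which therefore tests nothing further. Whether the members vary together stays open. With an estimated correlation the adjusted p was 0.97 (unadjusted 0.0392), but the estimate was -0.0188, below the preset 0.01, so the lost call comes from testing on 2 residual degrees of freedom and does not show such variation. In the additive fit, on which its calls at 2, 6 and 24 h in G-CSF rest, the estimate for the list was 0.288, above the preset. For those calls members varying together stays open too. Fewer cells in cycle may also account for it. The S phase list had a median of -0.0501, with 28 of 43 members below 0 (camera adjusted p 0.373). In ASXL1-MT minus mock it stood at percentiles of 43.5, 80.8, 55.0 and 4.34 at IL-3, 2, 6 and 24 h. Its median is too near 0 to decide. With 1 array of each culture at 24 h, a technical and a biological cause cannot be told apart.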

How the results depend on the processing

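The list tests under the stricter filter, quantile normalization, probe set means and left-out arrays, the bright-gene correlations and the probe set means of list members, were chosen only after the results were seen. Over the counts and correlations, 69 values under alternatives stayed within their limits and 60 did not. The correlations had no limit and were all counted among the 60. Over single genes and lists, 1095 kept direction and side of the threshold, 278 lost their call, 3 gained one and 3 reversed. The cause was not tested.

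For ASXL1-MT against mock, the stricter filter called 1 gene (Adora3, 1.10, adjusted p 0.0124) and the fit without time block 2 (Rbm46 and Ap5s1). Adora3 and Ap5s1 were named after their values were seen. The stricter filter tests fewer genes and also estimates the prior spread anew, and these were not told apart. All other alternatives gave 0. At an unadjusted p under 0.05 in limma were 683 to 964 of 12983 genes, 1004 of 18193 without a filter and 1455 of 23583 probe sets. The difference at 24 h gave 0 throughout and has no value without the 24 h arrays. For it limma had 691 to 826 of 12983 genes at an unadjusted p under 0.05. The stricter filter gave 390 of 7585 genes, no filter 1131 of 18193 and all probe sets 1366 of 23583.

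At 2 h the count was 0 without a filter, 33 with the stricter one, 0 for the mean of probe sets, 3 for all probe sets (of Boll, Scd3 and Slc26a3), 20 with a trend, 15 without a vector block and 0 in the fit of 4 arrays, and 0 to 0 with 1 array left out. At 6 h it was 585 without a filter, 3423 with the stricter one, 1496 for the mean of probe sets, 0 in the fit of 4 arrays, and 0 to 570 with 1 array left out. At 24 h it was 1806 without a filter, 5708 for all probe sets, 0 in the fit of 4 arrays, and 0 to 2339 with 1 array left out (2144 without a 6 h array). Fits with fewer arrays have fewer residual degrees of freedom. Quantile normalization and centring moved the share of higher calls from 57.7% to 51.6% and 49.5% at 6 h, and from 55.5% to 49.5% and 46.9% at 24 h.

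The size rule at IL-3, 2, 6 and 24 h took 2413, 2555, 2487 and 2543 genes at 0.6 and 4141, 4272, 4341 and 4218 without a filter. With an estimated correlation, the lists called went from 8 to 0 for ASXL1-MT, 3 to 0 at 2 h, 11 to 0 at 6 h and 16 to 5 at 24 h. The stricter filter called 5 lists at 2 h. With 1 time point left out, 3 to 7 lists were called for ASXL1-MT; with 1 array left out, 1 to 2 at 2 h, 9 to 11 at 6 h and 13 to 16 at 24 h. Among bright genes r of the response was 0.12, 0.753 and 0.839, and the median r of the ASXL1-MT difference between time points 0.0745, against -0.00137. With the mean of a gene's probe sets, Sgip1 (0.6081) and Asxl1 (0.09935) in ASXL1-MT against mock and Maf at 2 h (0.02611) reversed. Outside these counts, the list members Mycn (0.32) and Hoxa3 (-0.03) in ASXL1-MT against mock turned sign too.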

Other observations

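The contrasts between time points in G-CSF, and the tests of a whole-array shift, of a smaller or slower response, of the normalization and of a culture difference, were chosen only after the results were seen; the splits and swaps of arrays and the test of brightness were set earlier, apart from the swaps for the gene count. Between 6 and 24 h in G-CSF, 412 genes rose and 358 fell, and 20 of 31 mature neutrophil genes, 12 of 18 secondary granule genes and 11 of 26 STAT3 and G-CSF targets rose, each list being called also with an estimated correlation (adjusted p = 0.0409). Ngp rose by 4.80 ± 0.26 and Clec5a by 3.48 ± 0.39. Of 27 STAT5 and IL-3 targets 6 rose, led by the interleukin-2 receptor chain Il2ra (4.22 ± 0.20), at an adjusted p of 3.17e-07 (adjusted p = 0.127 with an estimated correlation). Cd200r3 fell by 2.37 ± 0.14 and Il5ra by 1.29 ± 0.18, after their rise by 6 h. Between 2 and 6 h, 1237 genes rose and 800 fell, among them 30 of 40 ribosome biogenesis genes downward (adjusted p 1.29e-22, or an adjusted p = 0.134 with an estimated correlation).

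Lists of other programs and cell types were not called at 24 h. Of 20 monocyte, macrophage and dendritic cell genes 8 rose, with the chemokine Ccl6 at 3.76 ± 0.15 and the receptor Csf1r at 1.65 ± 0.08, and 1 fell (adjusted p 0.118). Of 32 Polycomb and ASXL1 complex genes 5 rose, including Asxl1 itself (0.87 ± 0.09 by the probe set used, 0.43 by its other bright one), and 4 fell, including Bmi1 (-0.82 ± 0.10; list adjusted p 0.325). In the mast cell, basophil and eosinophil list 8 of 20 rose and 4 fell (adjusted p 0.0756), and of the STAT5 and IL-3 targets 11 rose and 7 fell (adjusted p 0.773). The stem and progenitor list had 4 higher and 3 lower (1 and 4 with the mean of all probe sets of a gene), with Slamf1 at -1.77 ± 0.13 (-2.83 for the mean of its probe sets; adjusted p 0.773), the megakaryocyte list 4 and 4 (adjusted p 0.773), the erythroid list 2 and 3 (adjusted p 0.443), the p53 list 5 and 2 (adjusted p 0.942) and the unfolded protein response list 1 and 3 (adjusted p 0.518). The HOX list had 1 higher (adjusted p 0.614), and no member passed in the lymphoid (adjusted p 0.614) or fibroblast list (adjusted p 0.606).

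Of 4743 probe sets without a gene symbol, limma called 0 in each of the 4 comparisons of vector and of G-CSF, with 225 for ASXL1-MT and 382, 891 and 1102 at 2, 6 and 24 h at an unadjusted p under 0.05, against 237 expected.

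Over the 32 of 35 splits of the 8 arrays into 4 and 4 that could be fitted, all 32 gave as many genes past the FDR as the real split (highest other 1); the real count of 0 fixes this outcome, so it tests nothing. For the 843 genes at an unadjusted p under 0.05, 1 of the 32 splits, the real one, gave as many (highest other 736), but 24 of them put both arrays of some time points in 1 group and so break the pairing of the cultures. The comparison that keeps the pairs has 8 swaps of the cultures within time points, too few for a share under 0.05. Over these the highest other gene count was 591, and the real arrangement called 8 lists and the highest other 1.

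A pattern noticed in the data ran across the lists: genes that rose in G-CSF at 24 h lay lower, and genes that fell lay higher, in the ASXL1-MT culture. The gap between the medians of the 1922 and the 1541 genes was -0.117, -0.085, -0.136 and -0.129 at IL-3, 2, 6 and 24 h (mean -0.117 ± 0.0225, SD, n = 4; the smallest exact p this design allows is 0.125), and the highest other of 8 swaps was 0.0742 in size. A uniform shift of whole arrays moves all genes alike and so cannot make a gap. At 4 of 4 time points the medians lay on opposite sides of that of all genes. After subtracting the gap of brightness-matched genes a mean gap of -0.128 was left, which argues against a shift between dim and bright genes. A shift that depends on brightness among bright genes stays open. Of the probe sets, 29.4% have an estimated level within 1 unit of 12, where brightness cannot be told apart. The gap in IL-3 was 91.2% of that at 24 h, but this cannot decide on a smaller or slower response to G-CSF. These genes passed a fit that treats any difference in response between the cultures as error, which favours genes that responded alike. The normalization of the table could still contribute, as the gap after quantile normalization was -0.0453, -0.0189, -0.16 and -0.019 at IL-3, 2, 6 and 24 h (mean -0.0608, carried by 6 h), and that step also evens out the spread between arrays. With 1 culture per vector a culture difference unrelated to the transgene and an effect of ASXL1-MT cannot be told apart.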
